A study of Mus musculus with 43 samples.

How the data were processed

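Total RNA of 43 fractions from 5 mouse brains was amplified linearly to Cy3-labelled cRNA and hybridised to 1-colour Agilent whole-genome arrays, 1 array per fraction, per the labels' protocols. The arrays were scanned and quantified with Agilent Feature Extraction version 10.5.1.1, and 1 array (C fraction 9) with version 10.10.1.1, per the file headers. The deposited scanner files hold the processed signal as an intensity, which Feature Extraction had background-subtracted, detrended and floored within each array, per the file headers, together with raw median spot and local background intensities. A deposited table of the whole series holds log2 values of 44169 probes, and its scale was found by setting each column against the scanner file of the same array. Over 44041 shared probes it equalled log2 of the processed signal minus the 75th percentile of the array, with a median absolute difference of 0.00431 log2. Its column medians ran from −2.48 to −1.29, and it was not centred per gene. The genome build named in the headers is mm9, and no coordinates were used.

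Each array carried 59305 spots without controls, for 55681 probes. Control spots were left out, as were 173 probes marked as outliers on some array, and spots of 1 probe were averaged (399 probes were spotted repeatedly). No spot was saturated (0 of all spots). The value analysed was log2 of the processed signal minus the 75th percentile of the array. Probes were named through the RefSeq accessions in the scanner files and a reference gene table of assembly GRCm38.p6. This matched 27235 probes to 20660 symbols, while 1450 of 28685 probes with a RefSeq accession were not matched and 28446 probes in total stayed unnamed. A probe was tested if it was well above background on at least 2 of 43 arrays, and the probe with the highest mean stood for its gene, which left 18496 genes. Of 4793 genes with over 1 probe, 1062 had a pair of probes that correlated below 0 along the C series. A fold change is the highest over the lowest fraction. Where the lowest fraction was not well above background, the fold was taken against the higher of its own signal and the lowest signal among probes well above background on that array, and is given as at least that size. Precision is limited by the number of arrays.

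Groups were the 5 series, taken from the sample labels. Position was tested with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table, 1.5.0 of matrixStats and 2.0.0 of jsonlite), in 1 fit of all 43 arrays with a series mean and a natural cubic spline of fraction number with 3 degrees of freedom in each series, which left 23 residual and 2.48 prior degrees of freedom. The moderated F test over the spline terms of a series was adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. Mirror pairs and sides were tested within the S series with pair and side as factors, the L and R series with series, a spline of relative position and their interaction, and all 5 series by their means over fractions. Neighbouring and other pairs of fractions were compared by the difference between their mean Pearson correlations across genes, with exact permutation of the order in series of up to 8 fractions and 100000 random orders otherwise. Gene lists for regions, cell types, other tissues and housekeeping functions, 34 in number with 308 members, were fixed before the data were examined. Of these members, 294 were tested, 9 were not well above background on enough arrays and 5 had no matched probe. The range of a list's median profile was set against 10000 random lists matched on size and mean expression in 20 bins. A member of 2 lists counts in both.

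The rule for named genes was fixed before the data were examined. It takes the 6 genes with the largest fitted range in each series among those that passed and were well above background in at least 2 of its fractions. From each list it takes the 3 members with the largest fitted range in C among those that passed, or the 2 with the largest range where fewer than 2 passed. For the mirror test it takes the 5 largest differences in each direction among genes that passed, of which there were 0. For the side, level, shape and among-series tests it takes the 5 genes with the smallest p, passing over names that are only transcript or clone identifiers. Some genes that the rule takes are not reported here.

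Alternatives fixed beforehand were quantile normalization, the deposited log2 table, a filter of 22 arrays or none, the median over the probes of a gene, all probes each by itself, leaving out each fraction, a quadratic curve, a fit to each series by itself, the slide as a random block or as a fixed factor in L, other middles of the S series at fraction 5 or 6, the R series numbered from the other end, and L against R without a spline. A planned normexp background correction on mean spot signals was not run because median signals were used here, and normexp with an offset of 50 on these was run in its place. Same-numbered fractions were checked for pairing by the correlation across genes of their deviations from the series means. All 7 pairs of L and R fractions correlated above 0.1 (0.113 to 0.56), which held for no other pair of series, so L and R were also fitted with the fraction number as a replicate block over fractions 1 to 7, with 6 residual degrees of freedom. This paired fit, a fit of all 5 series with the fraction number as a block, the normexp correction, a filter of all 43 arrays, the array's log2 75th percentile as a covariate, and fits to C fractions 1 to 8 and R fractions 2 to 6 were added after the data had been seen. Slides were read from the file headers: the arrays lay on 10 slides and were read in 10 scans on 2 scanners.

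Each test was tested on simulated data made from the means and residual spreads of the 18496 genes. The noise was independent between genes and arrays, so that shifts shared by many genes on 1 array were not simulated. The false calls below therefore leave out such shifts. In each test, 100 genes were changed by at most 1 log2 and 100 by at most 2 log2, along the curve or between its groups. The position test recovered 25 and 73 of these in C, 1 and 46 in H, 9 and 60 in L, 5 and 60 in R, and 18 and 65 in S, with 4, 3, 9, 1 and 2 false calls. The mirror test recovered 1 and 30 (5 false), the side test 68 and 91 (8 false), the L against R level test 71 and 88 (8 false) and its paired fit 61 and 88 (12 false), the shape test 0 and 0 (0 false), and the among-series test 49 and 88 (6 false), or 67 and 87 with the fraction number as a block (7 false). Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.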

Results

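Gene expression was mapped along the axes of the whole mouse brain by transcriptome tomography, in which a frozen organ is sliced from end to end, neighbouring slices are pooled into consecutive fractions, and each fraction is hybridised to its own array. The animals were 5 male littermates of R6/2 mice, a strain that carries a fragment of mutant human huntingtin and models Huntington disease, and these 5 did not carry the disease genotype. They were 5 weeks old. Each brain was sliced in 1 plane, with 200 slices of 5 µm in a fraction 1000 µm wide. Mouse 1 was cut coronally into 12 fractions (C series), mouse 2 horizontally into 6 (H series), mouse 3 in a left oblique plane into 8 (L series), mouse 4 in a right oblique plane into 7 (R series) and mouse 5 sagittally into 10 (S series). The labels number the fractions from 1 without naming the anatomical end, so positions are given below by number. On the 43 arrays, the 75th percentile of the processed signal lay between 52.4 (R fraction 1) and 619 (C fraction 8), and the share of probes well above background was highest in C fraction 12 (74.4%) and lowest in R fraction 1. No position was sampled more than once. The limma p-values of position therefore set changes along 1 series against the scatter of single fractions around smooth curves, pooled over all 5 series. Those of the other comparisons rest on the scatter of single fractions within mirror pairs, around a curve or around series means. None of these p-values measures the spread between animals, and the number of arrays limits their precision. The design asks at which positions along each axis a gene is expressed.

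Along the coronal series, the fractions passed from tissue rich in hindbrain transcripts to tissue rich in olfactory transcripts. Hox genes, the homeodomain factors that pattern the hindbrain and spinal cord, were highest in fraction 1, transcripts of cerebellar neurons in fractions 2 to 4, those of hippocampus and midbrain dopamine neurons in fraction 5, those of thalamus and hypothalamus in fraction 7, striatal transcripts in fractions 8 and 9, and olfactory bulb transcripts in fractions 11 and 12. Of 18496 genes tested, 13055 (70.6%) depended on position in this series, with a median fitted range, the highest minus the lowest fitted value, of 1.49 log2. A fitted range above 1 log2 was found in 10990 of these genes, of which 3132 were highest in fraction 1, 2761 in fraction 12, 1666 in fraction 8 and 1348 in fraction 7. Of the same 10990 genes, 6448 were lowest in fraction 12 and 1609 in fraction 1. The medians of all tested genes were lowest on the arrays of fractions 11 and 12 (−0.59 and −0.47). Of the 294 tested members of the 34 gene lists fixed beforehand, 231 depended on position, and 232 did so when adjusted over the list alone. Counts of list members along this series stand against the 70.6% of all genes, and those near that share do not set a list apart.

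**Figure D1:**
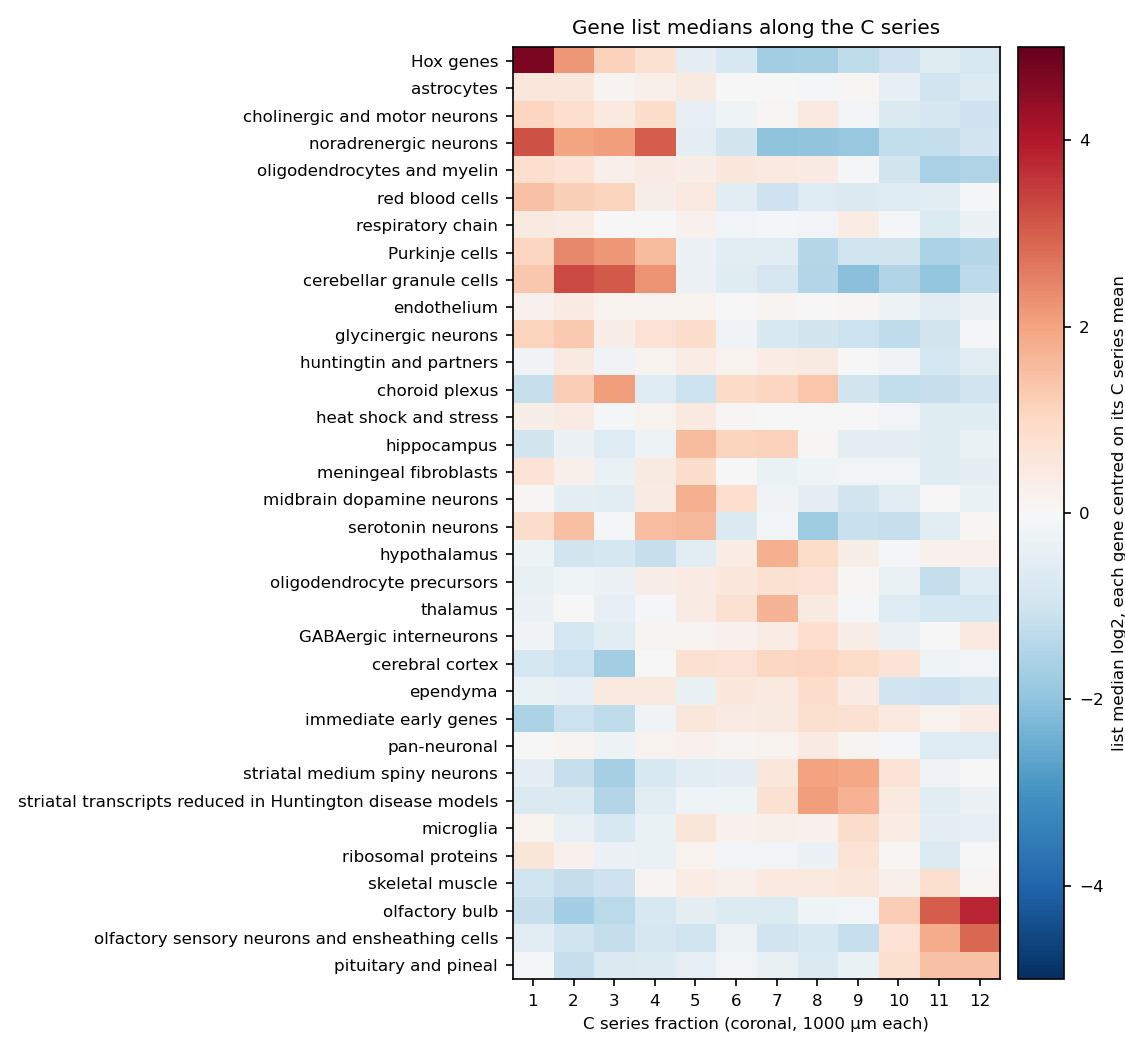
Median log2 value of each of 34 gene lists (vertical axis) in the 12 C series fractions (horizontal axis), after each gene was centred on its mean in the series; red is above and blue below that mean. Hox genes reach 4.72 in fraction 1, cerebellar granule cell genes 3.30 in fraction 2, striatal genes 2.02 in fraction 8 and olfactory bulb genes 3.82 in fraction 12.

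At the first fractions of the C series, 17 of 18 Hox genes depended on position (17 adjusted over the list alone), and their median was 4.72 log2 above the series mean in fraction 1. The fitted range was 8.50 ± 1.11 log2 (SE) for Hoxb4 (adjusted p = 1.26e-05), 8.26 ± 1.37 for Hoxb5 and 7.63 for Hoxc4. Hoxb4 was at least 78.8-fold higher in fraction 1 than in its lowest fraction, where it was not well above background. Bpifa6, outside the lists, was also highest in fraction 1, at least 430-fold above fraction 8. Of 4 noradrenergic genes, 3 depended on position (3 adjusted over the list alone), with list medians of 3.18 in fraction 1 and 3.03 in fraction 4. Among them Phox2a, a transcription factor of noradrenergic neurons, had a range of 5.62 ± 1.00, and Dbh, which makes noradrenaline from dopamine, was highest in fraction 4. Serotonin neuron genes depended on position in 4 of 5 cases (4 adjusted over the list alone), with medians of 1.49, 1.55 and 1.62 in fractions 2, 4 and 5. The serotonin transporter Slc6a4 and Tph2, the rate-limiting enzyme of brain serotonin synthesis, were both highest in fraction 4, at least 37.7-fold and 14.5-fold above their lowest fractions. The call of Slc6a4 ended without fraction 4, 8 or 9 (adjusted p = 0.0833, 0.0522 and 0.0531) and that of Tph2 without fraction 2 or 4 (adjusted p = 0.0512 and 0.0598). Gata3, a transcription factor of serotonin neurons, was highest in fraction 5. All 6 tested genes of the cholinergic and motor neuron list depended on position (6 adjusted over the list alone). Prph, a neurofilament of motor and sensory neurons, was highest in fraction 1, Calca, which encodes a calcitonin gene-related peptide, in fraction 4, and the homeodomain factor Isl1 in fraction 9. Of 3 tested glycinergic genes, 2 depended on position (3 adjusted over the list alone), namely the glycine receptor subunit Glra1, highest in fraction 1, and the glycine transporter Slc6a9, highest in fraction 2.

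Cerebellar transcripts peaked next. All 9 Purkinje cell genes depended on position (9 adjusted over the list alone), as did 8 of 9 granule cell genes (8 adjusted over the list alone), and both list medians were highest in fraction 2, at 2.40 and 3.30. Pcp2, a modulator of G protein signalling specific to Purkinje cells and retinal bipolar cells, had a fitted range of 6.82 ± 0.50 (adjusted p = 1.52e-09) and was 90.1-fold higher in fraction 2 than in fraction 8. Ppp1r17, a phosphatase inhibitor of Purkinje cells, and Car8, a carbonic anhydrase-related protein, had ranges of 6.09 ± 0.56 and 4.85 ± 0.61. Among granule cell genes, the GABA-A receptor subunit Gabra6 had a range of 6.83 ± 0.71 and was at least 360-fold higher in fraction 2 than in fraction 11, the secreted synapse organiser Cbln3 had a range of 6.71 ± 1.03, and the homeodomain factor En2 had a range of 4.85 ± 0.53. Of 8 genes of GABAergic interneurons, 5 depended on position (5 adjusted over the list alone) with different peaks. The calcium buffer Pvalb, which Purkinje cells also express, was 36.4-fold higher in fraction 2 than in fraction 11, while the neuropeptides Sst and Vip were highest in fractions 8 and 10.

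In the middle fractions, 7 of 9 hippocampal genes depended on position (7 adjusted over the list alone), with the list median highest in fraction 5 (1.57). Spink8 was highest in fraction 6, Fibcd1 in fraction 5, and Tdo2, the tryptophan dioxygenase, in fraction 3. Fibcd1 lost its call without fraction 2 (adjusted p = 0.0653) or fraction 6 (0.0534). Midbrain dopamine genes depended on position in 5 of 9 cases (5 adjusted over the list alone), with a median of 1.76 in fraction 5. Aldh1a1, a retinoic acid-forming enzyme, was 12.9-fold higher in fraction 2 than in fraction 11, and Ret, the signalling receptor for glial cell line-derived neurotrophic factor, was highest in fraction 5. Th, the rate-limiting enzyme of dopamine synthesis, was high at both ends of this stretch, at 4.54 in fraction 5 and 5.14 in fraction 12. Its call ended without fraction 12 (adjusted p = 0.335) or fraction 11 (0.137). Thalamic genes depended on position in 9 of 11 cases (9 adjusted over the list alone) and were highest in fraction 7 (median 1.71). The slow troponin Tnnt1 was 16.6-fold higher in fraction 6 than in fraction 2, and the protein kinase C isoform Prkcd was 22.4-fold higher in fraction 7 than in fraction 11. Prkcd did not pass without fraction 11 (adjusted p = 0.0566), and the homeodomain factor Shox2 did not pass when any 1 of fractions 4 to 11 was left out. Hypothalamic genes depended on position in 8 of 14 cases (8 adjusted over the list alone), again highest in fraction 7 (median 1.76). The hormone precursors Avp (vasopressin) and Oxt (oxytocin) had ranges of 7.43 ± 1.41 and 6.27 ± 1.27, with the highest values in fractions 7 and 8, while Otp, a homeodomain factor of neuroendocrine neurons, was highest in fraction 11. C fractions 10 to 12 shared a slide with H fractions 1 to 4. There Otp lay at −2.00, −5.21, −3.39 and −3.07, against −6.41 and −5.59 in H fractions 5 and 6 on another slide. For Otp, position and slide cannot be told apart.

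All 15 genes of striatal medium spiny neurons depended on position (15 adjusted over the list alone), as did all 12 striatal transcripts that are reduced in Huntington disease models (12 adjusted over the list alone). The 2 lists share members. Their medians were 2.02 and 2.08 in fraction 8, against −1.68 and −1.45 in fraction 3. The dopamine receptor Drd1 had a fitted range of 5.88 ± 0.61 (adjusted p = 2.69e-07) and was at least 66.6-fold higher in fraction 8 than in fraction 2. The adenosine receptor Adora2a, marker of the indirect pathway, was 53.1-fold higher in fraction 8 than in fraction 5, Rgs9, a regulator of G protein signalling, 89.4-fold higher in fraction 9 than in fraction 3, and the phosphoprotein Arpp21 48.2-fold higher in fraction 8 than in fraction 3. Of the 7 tested genes of huntingtin and its partners, 6 depended on position (7 adjusted over the list alone), with smaller ranges. The range of this list's median was at percentile 83.3 of matched random lists. The palmitoyltransferase Zdhhc17 had a range of 1.86 ± 0.33, the clathrin adaptor Hip1r 1.56 ± 0.32 and the neuronal gene silencer Rest 1.43 ± 0.34, each lowest in fraction 11. Huntingtin itself, Htt, which was singled out after its values were seen, had a fitted range of 1.31 ± 0.27 (adjusted p = 8e-04) and was 2.75-fold higher in its highest than in its lowest fraction. All 11 genes of the cerebral cortex depended on position (11 adjusted over the list alone), with medians of 1.04, 1.06 and 0.91 in fractions 7, 8 and 9. The transcription factors Tbr1 and Fezf2, which specify projection neurons, had ranges of 6.52 ± 0.73 and 5.68 ± 0.77. Immediate early genes, which neuronal activity induces, depended on position in 9 of 10 cases (9 adjusted over the list alone) and were also highest in fraction 8 (median 0.79). Egr2, Arc and Egr1 had ranges of 5.93 ± 0.48, 3.31 ± 0.46 and 3.25 ± 0.32.

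**Figure D2:**
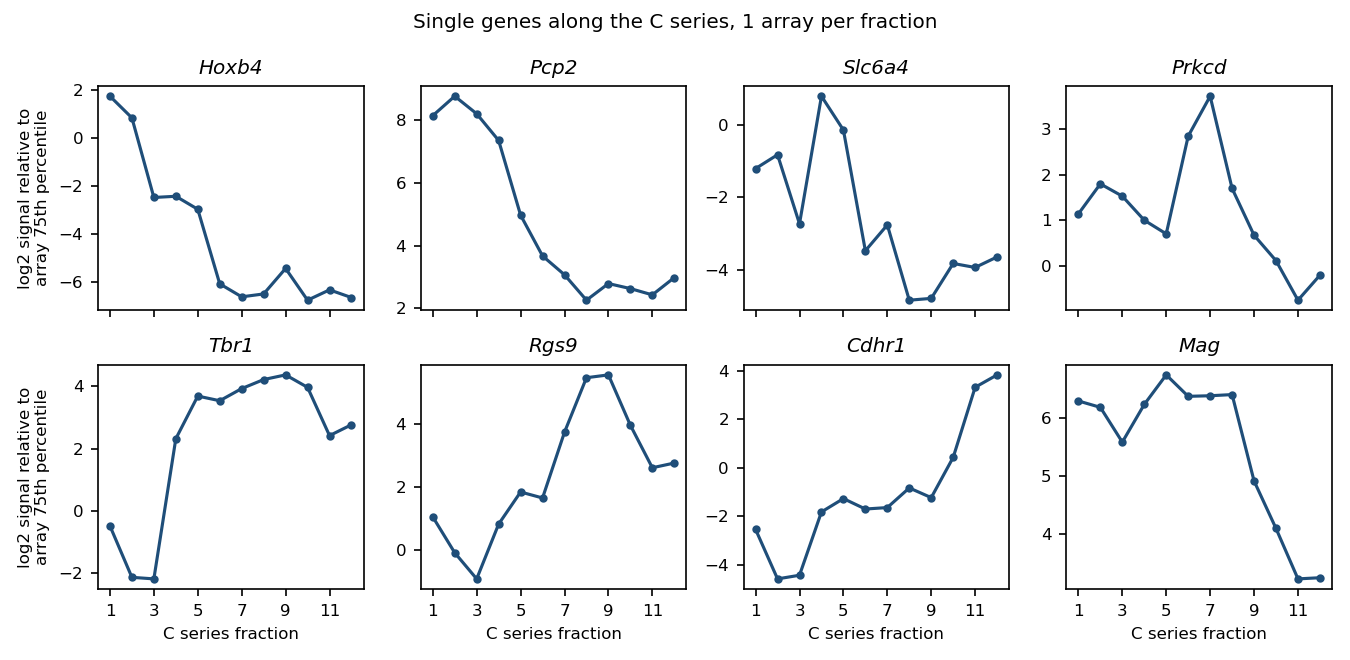
Log2 signal relative to the 75th percentile of the array (vertical axes) of 8 genes in the 12 C series fractions (horizontal axes), 1 point per array. The peaks shift from fraction 1 for Hoxb4 and fraction 2 for Pcp2 to fraction 7 for Prkcd, fraction 9 for Rgs9 and fraction 12 for Cdhr1, and Mag is lowest in fraction 11.

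At the other end, 9 of 10 olfactory bulb genes (9 adjusted over the list alone) and 4 of 6 genes of olfactory sensory neurons and ensheathing cells (4 adjusted over the list alone) depended on position, with medians of 3.82 and 2.88 in fraction 12. Cdhr1, a cadherin of mitral and tufted cells, had a range of 7.96 ± 1.07 and was at least 322-fold higher in fraction 12 than in fraction 2. Dlx2, a homeodomain factor of GABAergic interneuron precursors, had a range of 7.93 ± 0.84 (adjusted p = 1.38e-08), and Tbx21, a T-box factor of mitral and tufted cells, 7.46 ± 0.93. The largest fitted ranges of the series were those of Ms4a15 (11.16 ± 1.56), S100a5, a calcium-binding protein of olfactory sensory neurons (9.75 ± 1.04), and Omp, the olfactory marker protein of mature sensory neurons (8.75 ± 1.08). S100a5 was 521-fold and Omp 409-fold higher in fraction 12 than in its lowest fraction, and Ms4a15 at least 298-fold. Stoml3, a stomatin-like protein of olfactory cilia, was at least 20.6-fold higher. The median of pituitary and pineal genes was highest in fraction 12 (1.47), and 5 of 8 depended on position (5 adjusted over the list alone). The range of this median was at percentile 92.2 of matched random lists. Cga and Tshb went the other way and were highest in fraction 7 (0.26 and −1.33), against −6.41 and −4.90 in fraction 12. Among the genes that passed, Lhb, the beta subunit of luteinising hormone, was 9.40-fold higher in fraction 11 than in fraction 2. Pou1f1, a pituitary transcription factor, and Prl, prolactin, were well above background in 3 and 2 of 12 fractions. Their calls ended with quantile normalization (limma, adjusted p = 0.202 and 0.122). C fractions 10 to 12 lay on another slide than 1 to 8, shared with H fractions 1 to 4. In H, the list median was 0.15 to 0.64 in fractions 1 to 4 and −1.75 and −1.15 in 5 and 6, on another slide. Lhb lay at −1.24 to −0.74 and at −2.19 and −2.59 there. Position and slide cannot be told apart for this rise.

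Glial, vascular and housekeeping transcripts had smaller ranges, and most of these lists were lowest in fraction 11. There the median of all tested genes was −0.59 relative to the 75th percentile of the array, against −0.47 in fraction 12 and −0.18 to −0.39 in the other C fractions. Quantile normalization moved that median by −0.30 in fraction 11 and −0.16 in fraction 12. Genes of oligodendrocytes and myelin depended on position in 11 of 12 cases (11 adjusted over the list alone), with medians of 0.85 in fraction 1 and −1.61 in fraction 11. Mbp, the myelin basic protein, had a range of 3.74 ± 0.53, the myelin adhesion molecule Mag 3.69 ± 0.44 and Ugt8a, which makes galactocerebroside, 3.10 ± 0.43. Oligodendrocyte precursor genes depended on position in 5 of 6 cases (5 adjusted over the list alone), among them Enpp6, Gpr17 and the growth factor receptor Pdgfra. All 9 astrocyte genes (9 adjusted over the list alone) depended on position, with ranges of 2.96 ± 0.48 for the filament protein Gfap, 2.49 ± 0.33 for the water channel Aqp4 and 1.79 ± 0.27 for the connexin Gjb6. Microglial genes did so in 7 of 9 cases (7 adjusted over the list alone), and P2ry12 and Cx3cr1 were both highest in fraction 9. That array was the only one of its slide and scan and was read with another software version, and the medians of both microglial (0.88) and ribosomal protein genes (0.69) were highest there. Without it, 5 of 9 microglial genes passed (5 adjusted over the list alone), P2ry12 and Cx3cr1 among them. Of 9 endothelial genes, 5 depended on position (5 adjusted over the list alone), including Ly6c1, Itm2a and the tight junction protein Cldn5, whose call ended without fraction 1 (adjusted p = 0.0625) or 11 (0.0541). Of 9 meningeal fibroblast genes, 6 did (6 adjusted over the list alone), and the matrix genes Lum, Col3a1 and Dcn had ranges of 1.78, 1.56 and 1.38. Of 3 red blood cell genes, 2 depended on position (3 adjusted over the list alone), namely Alas2, the first enzyme of erythroid haem synthesis, and the globin Hba-a1, both highest in fraction 1.

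Choroid plexus genes had 2 peaks, with medians of 2.10 in fraction 3 and 1.40 in fraction 8, but only 2 of 11 depended on position (2 adjusted over the list alone), the anti-ageing hormone Kl and the homeodomain factor Otx2, which was 9.16-fold higher in fraction 3 than in fraction 10. Kl lost its call without fraction 11 (adjusted p = 0.088). Ependymal genes depended on position in 4 of 7 cases (4 adjusted over the list alone), among them Tmem212, Ccdc153 and Rarres2. Pan-neuronal genes did so in 6 of 7 cases (6 adjusted over the list alone), with ranges of 2.25 ± 0.27 for the synaptic calcium sensor Syt1 and 1.89 for both the vesicle protein Syp and the tubulin-binding protein Stmn2. All 6 tested heat shock and stress genes (6 adjusted over the list alone) depended on position, including Atf3, Hspb1 and Dnajb1, as did 7 of 8 respiratory chain genes (7 adjusted over the list alone), including Ndufs1, Cycs and Uqcrc1. Of 8 ribosomal protein genes, 3 depended on position (1 adjusted over the list alone), and Rps6, Rpl3 and Rps9 had ranges of 1.68, 1.13 and 1.05. Without fraction 1, neither Rpl3 nor Rps9 passed (adjusted p = 0.238 and 0.42), Rps9 also lost its call without fraction 2 (0.0562), and Rpl3 without fraction 2, 4, 10 or 11 (0.0505 to 0.116). Skeletal muscle genes, a control for tissue outside the brain, depended on position in 4 of 6 cases (4 adjusted over the list alone). Ckm, the muscle creatine kinase, was well above background in 1 of 12 fractions and did not pass without fraction 12 (adjusted p = 0.102), whereas Myh4 and Myh1, fast myosins, were highest in fractions 5 and 10.

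Of the 34 lists, 24 had a median profile with a range above the 95th percentile of 10000 random lists of the same size and mean expression. Lists that fell short were those of pan-neuronal (percentile 21.7), endothelial (27.6), respiratory chain (38.4), skeletal muscle (67.2) and heat shock and stress genes (68.2). So did those of ribosomal proteins (79.4), huntingtin and partners (83.3), pituitary and pineal (92.2), glycinergic neurons (93.8) and meningeal fibroblasts (94.5). Neighbouring C fractions correlated at a mean r of 0.348 across genes and other pairs at −0.167, a difference of 0.515, and none of 100000 random orders of the fractions reached it (permutation test, one-sided, p = 1e-05, the smallest that they can give, and 5e-05 after Benjamini-Hochberg adjustment over 5 series). These are correlations across genes, which are not independent replicates. Fitted without the other series, limma called 8011 genes in C and kept 84 of the 99 named genes. In the fit with the other series, but with C restricted to fractions 1 to 8, which share a slide, it called 4275.

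Along the horizontal series, the list medians of hypothalamic, striatal (0.88) and cholinergic and motor neuron genes (1.96) were highest in fraction 6, and those of cortical (0.61) and Purkinje cell genes (0.84), of which few members passed, in fraction 2. Here 905 genes (4.9%) depended on position, with a median fitted range of 2.21 log2. Among list members, 64 of 294 did, and 110 when adjusted over the list alone. The largest ranges were those of Avp (12.09 ± 2.40), Pmch, the precursor of melanin-concentrating hormone (10.38 ± 2.09), and Oxt (9.08 ± 1.78), each highest in fraction 6, where Avp was at least 736-fold above fraction 1. Trh, thyrotropin-releasing hormone, and Arhgap36, a regulator of protein kinase A, followed with 7.64 each, and Ms4a15, highest in fraction 5, with 8.76 ± 1.84. Hypothalamic genes depended on position in 8 of 14 cases (11 adjusted over the list alone), with a median of 3.25 in fraction 6. Cholinergic and motor neuron genes did so in 5 of 6 cases (5 adjusted over the list alone), with Isl1 at least 11.4-fold higher in fraction 6 than in fraction 2. Of 15 striatal genes, 8 depended on position (10 adjusted over the list alone), and Drd1 was 13.5-fold higher in fraction 6 than in fraction 1. Olfactory bulb genes did so in 5 of 10 cases (9 adjusted over the list alone), with Cdhr1 at least 63.5-fold higher in fraction 5 than in fraction 1. The S100a5 signal was 66.6-fold higher in fraction 5 than in fraction 1. Cortical genes passed in 2 of 11 cases (4 adjusted over the list alone) and Purkinje cell genes in 2 of 9 (6 adjusted over the list alone), and Pcp2 was 8.70-fold higher in fraction 2 than in fraction 6. Meningeal genes passed in 6 of 9 cases (8 adjusted over the list alone), with medians of 0.85 in fraction 1 and 0.83 in fraction 6. Myelin genes passed in 7 of 12 cases (11 adjusted over the list alone), with a median of −1.38 in fraction 1. Without fraction 6, the calls of Avp, Oxt, Pmch and Isl1 ended and 378 genes passed, without fraction 5 those of Oxt and Pmch ended and 465 passed, 558 passed without fraction 3, and without fraction 1 the calls of Drd1 and Cdhr1 ended and 370 passed. Ms4a15 did not pass without fraction 1, 2 or 5, and Pcp2 lost its call without fraction 1, 2, 3, 5 or 6.

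The mean correlation of neighbouring H fractions exceeded that of other pairs by 0.333, which did not pass the exact permutation test over all 720 orders (p = 0.122, one-sided, and 0.122 after adjustment over 5 series) but did without fraction 2 (p = 0.0167) and over genes well above background on all 43 arrays (p = 0.0139). Fitted without the other series, which leaves 2 residual degrees of freedom, limma called 0 genes, with 2170 at an unadjusted p below 0.05. With the slide as a random block, it called 287, and 7 of 100 orders of the H fractions, the numbered one included, gave 905 genes or more.

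In both oblique series, the list medians of granule and Purkinje cell genes were highest in fraction 2 and that of hypothalamic genes in fraction 7 (L) or 6 (R). In the left oblique series, 1147 genes (6.2%) depended on position. Avp, Oxt and Pmch had ranges of 8.52 ± 1.86, 8.32 ± 1.53 and 7.84 ± 2.00, with highest values in fractions 7, 6 and 6. Zfp866, a zinc finger gene, reached 8.34 in fraction 1 and lay between 0.11 and 0.93 in the other 7 fractions, so that its call (range 7.48 ± 0.77) rested on 1 array and ended without it. The calls of Dsg1c, a desmosomal cadherin, and Vmn1r197, a vomeronasal receptor, whose signals were also highest in fraction 1, ended without fraction 1, 3, 5, 7 or 8. Of the list members, 51 of 294 depended on position, and 102 when adjusted over the list alone. Purkinje cell genes did so in 6 of 9 cases (9 adjusted over the list alone) and granule cell genes in 5 of 9 (7 adjusted over the list alone), and Pcp2 and En2 were 13.1-fold and 13.2-fold higher in fraction 2 than in fraction 7. The call of En2 ended without fraction 2, 3 or 7. Hypothalamic genes passed in 8 of 14 cases (11 adjusted over the list alone) and striatal genes in 6 of 15 (13 adjusted over the list alone), with list medians of 1.94 in fraction 7 and 0.97 in fraction 6. Isl1 was at least 10.2-fold higher in fraction 6 than in fraction 2. The calls of Avp and Oxt ended without fraction 7, and that of Pmch without any 1 fraction. Myelin genes passed in 7 of 12 cases (11 adjusted over the list alone), with a median of −1.43 in fraction 1, and 2 of 18 Hox genes did (2 adjusted over the list alone).

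The exact permutation test over all orders of the 8 fractions gave a difference of 0.393 between neighbouring and other L fractions (p = 0.0346, one-sided), which did not pass after adjustment (0.0577). The L arrays lay on 2 slides. Fitted to L alone, limma called 0 genes with the slide as a fixed factor (5299 at an unadjusted p below 0.05) and 0 without that factor (4957 unadjusted). In the fit of all series, it called 139 with the array signal as a covariate, 294 without fraction 1, 296 without fraction 3 and 522 to 653 without fraction 2, 5 or 7. The correlation test did not pass without fraction 3, 4, 5 or 8 (p from 0.0893 to 0.186).

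In the right oblique series, 4089 genes (22.1%) depended on position, and 152 of 294 list members did (176 adjusted over the list alone). Avp (11.90 ± 1.85), Oxt (9.84 ± 1.67), Pmch (8.86 ± 2.12) and Trh (8.68 ± 1.32) were highest in fraction 6, where Oxt was 1020-fold above fraction 3. Cga and Tshb, subunits of pituitary glycoprotein hormones, were highest in fraction 7 and well above background in 2 of 7 fractions. Hypothalamic genes depended on position in 11 of 14 cases (11 adjusted over the list alone), with medians of 2.84 and 2.41 in fractions 6 and 7. Granule cell and Purkinje cell genes did so in 8 of 9 cases each (9 and 8 adjusted over the list alone), with Gabra6 12.8-fold higher in fraction 2 than in fraction 7. Of 18 Hox genes, 11 passed (11 adjusted over the list alone), with a median of 2.24 in fraction 4, and Hoxb4 was at least 14.3-fold higher in fraction 5 than in fraction 2. Striatal genes passed in 10 of 15 cases (12 adjusted over the list alone) and motor neuron genes in 6 of 6 (6 adjusted over the list alone), both highest in fraction 5, where Drd1 was at least 14.7-fold above fraction 1. Ependymal genes passed in 6 of 7 cases (6 adjusted over the list alone) and choroid plexus genes in 4 of 11 (7 adjusted over the list alone), both highest in fraction 4, where Otx2 was at least 30.9-fold above fraction 1. Fraction 1 had the weakest array of the study. It held the highest medians of meningeal genes (1.28, 9 of 9 passed, 9 adjusted over the list alone) and ribosomal protein genes (0.96, 8 of 8 passed, 8 adjusted over the list alone), and the lowest of myelin genes (−2.04, 11 of 12 passed, 11 adjusted over the list alone). Without fraction 1, 713 genes passed, and the calls of Trh, Cga, Tshb, Gabra6, Hoxb4, Drd1 and Otx2 ended. Pmch did not pass without fraction 6, Cga, Tshb and Gabra6 did not pass without fraction 7, nor Hoxb4 without fraction 2 or 3.

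The mean correlation of neighbouring R fractions exceeded that of other pairs by 0.289 (exact permutation test over 5040 orders, p = 0.0488, one-sided), which did not pass after adjustment (0.061) or without any 1 of fractions 3 to 7 (p from 0.0889 to 0.292). Fitted without the other series, limma called 0 genes in R (4733 unadjusted). In the fit with the other series, it called 452 with the array signal as a covariate. With R restricted to fractions 2 to 6, which share a slide, it called 67.

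Along the sagittal series, which runs from side to side, the medians of several lists peaked in the middle fractions and those of others towards both ends. Median levels of Hox genes were highest in fraction 5 (1.27), those of hypothalamic and midbrain dopamine genes in fraction 6 (1.42 and 1.37), and those of olfactory bulb genes in fraction 7 (1.54). Striatal genes had maxima in fractions 4 (0.67) and 9 (0.70) with −0.82 in fraction 6 between them, thalamic genes in fractions 4 (0.80) and 7 (0.50), and cortical genes in fractions 2 (0.57) and 9 (0.49). Of the 34 lists, 26 had a wider range than the 95th percentile of matched random lists. Single genes passed less often: 249 (1.3%) depended on position, and 11 of 294 list members did (43 adjusted over the list alone), among them 3 of 11 cortical genes (4 adjusted over the list alone) and 2 of 12 myelin genes (9 adjusted over the list alone). In limma, 0 of 18 Hox, 0 of 14 hypothalamic, 0 of 9 midbrain dopamine and 0 of 15 striatal genes passed along S, over all genes or adjusted over the list alone, with 3, 1, 5 and 1 at an unadjusted p below 0.05. The largest ranges were those of the phospholipase Plb1 (3.79 ± 0.48, adjusted p = 0.000146), highest in fraction 1 at at least 12.4-fold above fraction 6, and of Btnl1, Adamts13, a von Willebrand factor protease, Pigt, a subunit of the enzyme that attaches lipid anchors, Ttll6 and Prss16, with 3.11 to 3.39. Neighbouring S fractions correlated more than other pairs by 0.243 (permutation test, 100000 orders, one-sided, p = 0.00449, 0.0112 after adjustment), but not without fraction 6 (p = 0.06). Without fraction 1, 40 genes passed and the calls of Btnl1, Adamts13, Pigt and Prss16 ended, without fraction 7 or 8 that of Ttll6 ended, and without any 1 of fractions 2, 4, 5, 6 and 7 between 74 and 142 genes passed. Fitted without the other series, limma called 1182 genes.

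**Figure D3:**
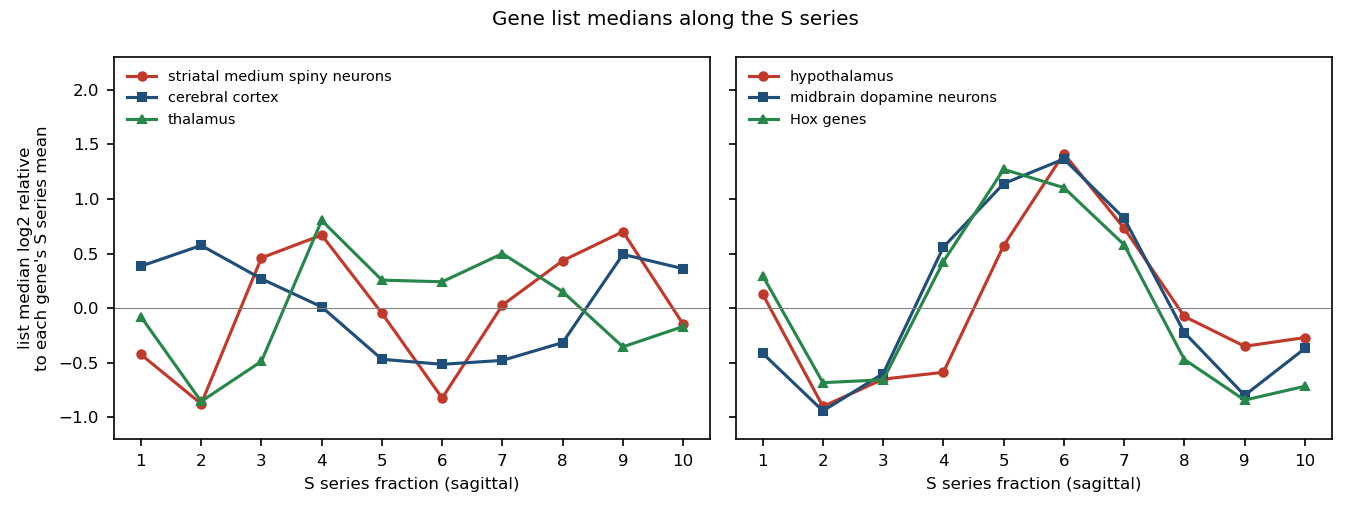
Median log2 value of 6 gene lists (vertical axes, each gene centred on its mean in the series) in the 10 S series fractions (horizontal axes). Striatal genes have maxima of 0.67 in fraction 4 and 0.70 in fraction 9, whereas hypothalamic, midbrain dopamine and Hox genes have 1 maximum, in fractions 5 and 6.

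Mirror pairs of sagittal fractions (1 with 10 to 5 with 6) were compared to ask which genes differ with distance from the middle of the series. That the midline lies between fractions 5 and 6 is an assumption, which the labels do not state. The difference of the innermost minus the outermost pair was taken for each gene. Its median over list members was 1.82 for midbrain dopamine genes, 1.73 for noradrenergic genes, 1.46 for Hox genes and 1.39 for hypothalamic genes. It was −0.75 for cortical genes, −0.75 for microglial genes and −0.76 for immediate early genes. No gene passed over all genes (limma, 0 of 18496, 3605 at an unadjusted p below 0.05). Adjusted over the list alone, 11 of 18 Hox genes, 10 of 12 myelin genes, 7 of 11 cortical genes, 7 of 9 dopamine genes, 6 of 9 microglial genes and 5 of 10 immediate early genes differed among the pairs, but 0 of 14 hypothalamic genes did (limma, 6 at an unadjusted p below 0.05). The mirrored fractions correlated at 0.411 (5 with 6), 0.246 (1 with 10), 0.091 (2 with 9), −0.129 (4 with 7) and −0.294 (3 with 8) across genes. Fractions 1 to 6 lay on 1 slide and 7 to 10 on another. The pair of 5 and 6, which are also direct neighbours, is therefore the only mirrored pair on 1 slide. Over genes well above background on all 43 arrays, 1520 passed. Between the sides, 0 genes passed (limma, 1475 unadjusted). The 5 genes with the smallest p (adjusted p = 0.543 each) were Lce1l, Cox17, Gm5938, Pxdc1 and Axin2. Lce1l, Cox17 and Gm5938 were well above background in 1 of 10 fractions each and Pxdc1 in no fraction, so that no difference is given for them. Axin2, a Wnt feedback inhibitor that was well above background in 7 of 10, had −1.04 ± 0.13 log2 in fractions 6 to 10 minus 1 to 5, with the same sign in 5 of 5 pairs. Side and slide nearly coincide, since of fractions 6 to 10 only fraction 6 shared the slide of fractions 1 to 5.

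The oblique series, cut in mirrored planes from different mice, were compared for level and for shape. The smallest p belonged to Hif3a, a hypoxia-inducible factor subunit, which was higher by 2.27 ± 0.11 log2 (adjusted p = 2.24e-06), Depp1, a gene induced by fasting and progesterone, by 1.63 ± 0.12, Ada, adenosine deaminase, by 1.62 ± 0.11, Paqr5, a membrane progestin receptor, by 1.32 ± 0.11, and Nfkbia, the inhibitor of nuclear factor kappa B, by 0.90 ± 0.10. All 7 R fractions lay above all 8 L fractions for each of these 5. In total 108 genes differed in level, 98 higher and 10 lower in R. Of the list members, 2 of 3 red blood cell genes and 1 of 9 endothelial genes were among them, all higher in R: Alas2 by 1.82 ± 0.20, Hba-a1 by 1.71 ± 0.25 and Ly6c1 by 0.92 ± 0.17. Adjusted over the list alone, 3 of 3 red blood cell, 2 of 9 endothelial, 7 of 8 ribosomal protein, 6 of 9 microglial and 5 of 8 respiratory chain genes differed, and of these the 3 red blood cell genes and 1 endothelial gene did with the slide as a random block. With the slide as a random block, limma called 4 genes, Ada, Depp1, Hif3a and Paqr5. With the fraction number as a block over the 7 pairs of same-numbered fractions, it called 43 genes, 40 of them higher in R, and 36 of the 43 were among the 108. The count was 6168 with normexp, 2729 with no filter on dim probes, 1677 over genes well above background on all 43 arrays, 31 without the spline, 58 with the R fractions numbered from the other end, 3518 without R fraction 4 and 1527 without R fraction 2, and between 43 and 71 without any 1 of R fractions 1, 3, 5, 6 and 7 and L fractions 1, 2, 4, 5, 7 and 8. For shape, 0 genes passed (limma, 1207 unadjusted), and the smallest p belonged to Tmem168, Rsph6a, Mc3r, a melanocortin receptor, 4430402I18Rik and Uevld (adjusted p = 0.546 each). On simulated data this test recovered 0 of 100 genes at either size of change, so that it had little power for such changes in few genes. In another, random split of the same fractions it called 1075 genes. That split mixed mice and slides and holds no known difference in shape, so it does not show what the test can find. Mouse, cutting plane and slide cannot be told apart in these comparisons.

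**Figure D4:**
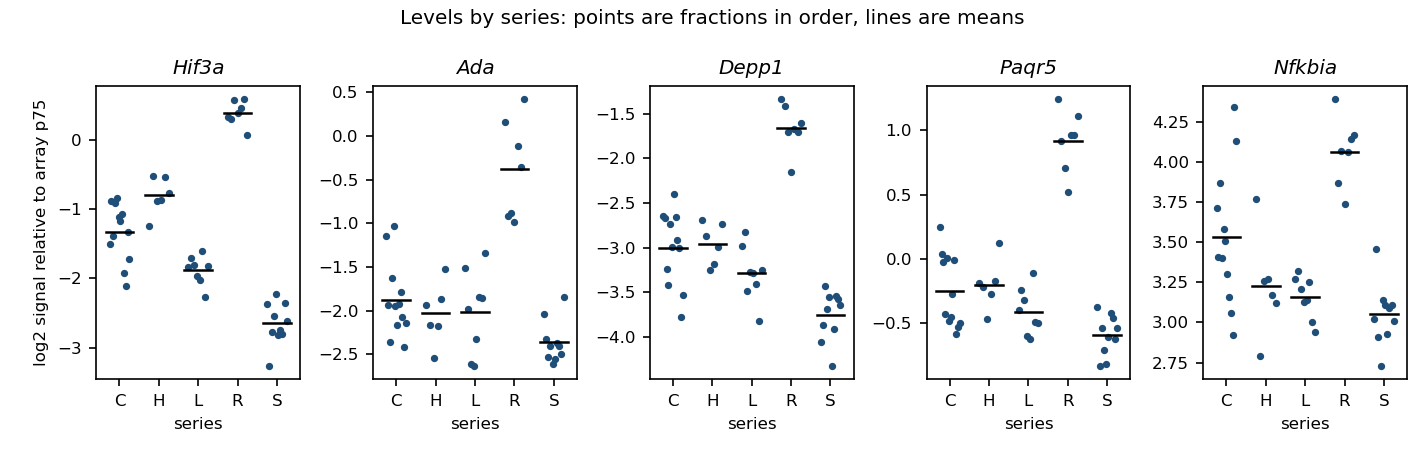
Log2 signal relative to the 75th percentile of the array (vertical axes) of 5 genes in the 5 series (horizontal axes); each point is 1 fraction, in order from left to right, and lines are series means. The 7 R fractions of Hif3a lie between 0.06 and 0.58 and the 8 L fractions between −2.27 and −1.60.

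Across all 5 series, 8102 genes differed in mean level (9719 unadjusted), of which 3969 were highest in R and 3147 lowest in H. Hif3a again had the smallest p (adjusted p = 9.86e-17), with means of 0.38 ± 0.18 (SD, n = 7) in R, −0.80 ± 0.27 (SD, n = 6) in H, −1.33 ± 0.42 (SD, n = 12) in C, −1.88 ± 0.21 (SD, n = 8) in L and −2.65 ± 0.30 (SD, n = 10) in S, where n counts fractions of 1 mouse. Of the other 2 probes of Hif3a, 1 had the same order of series, with −3.50 in R and −5.62 in L, and the other was lower in R (−5.53) and L (−5.71) than in C (−3.27) and H (−3.39). The means of the first of these in L and S, and of the second in R and L, lay below the lowest signals well above background on those arrays. The order of those series is therefore one of background values. Usp8, a deubiquitinating enzyme, had means of 2.77 in C, 2.54 in H and 1.76 in S against 0.01 in L and −1.12 in R. Papola, a poly(A) polymerase, gave 2.76, 2.56 and 2.04 against 0.68 and 0.35, and both genes were measured by 1 probe each. The L and R arrays shared no slide or scan with those of C, H or S. For Usp8 and Papola, series and slide cannot be told apart. Paqr5 and Depp1 were highest in R, at 0.92 and −1.66. All 9 microglial genes differed among the series, and 6 each of 9 endothelial genes, 8 ribosomal protein genes and 10 immediate early genes. With the slide as a random block, 1720 genes passed. On the slides that held fractions of 2 series, 67 genes differed between 3 C and 4 H fractions, and 0 between 2 H and 6 S fractions (limma, 2138 unadjusted). Fractions of a series cover different tissue, so that a difference in mean level can also follow from which tissue was sampled.

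**Figure D5:**
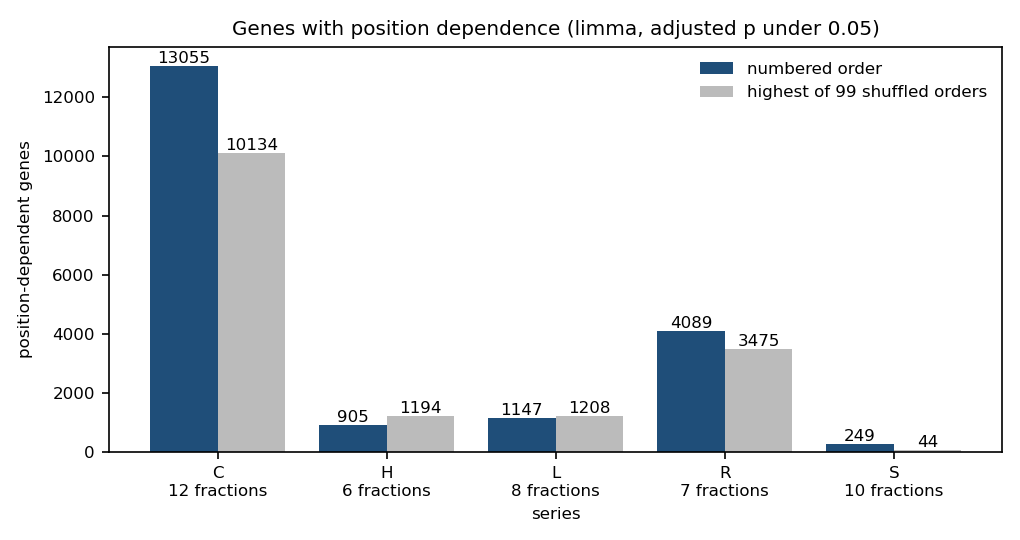
Number of position-dependent genes (vertical axis) in each series (horizontal axis) in the numbered order of fractions (blue) and the highest number among 99 random orders of that series with the others kept in numbered order (grey). The numbered order gives more in C (13055 against 10134), R (4089 against 3475) and S (249 against 44), but not in H (905 against 1194) or L (1147 against 1208).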

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

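The fits with the array signal as a covariate and over C fractions 1 to 8, the paired fit of L and R, the check on genes well above background on all 43 arrays in L the check of shared slides in L and the reordering of 1 series at a time were chosen only after the pattern they bear on was seen. Within series of 6 to 10 fractions, 7 of 152 measures (4.6%) had an extreme fraction set apart from the others, where chance alone sets 1 apart in about 1 in 20 groups. Myelin genes had a median of −1.38 in H fraction 1, with the nearest other fraction at 0.02, and of −2.04 in R fraction 1, with the nearest at −0.18. Genes of GABAergic interneurons had a median of −0.42 in L fraction 1 (nearest −0.09). In S fraction 1, granule cell genes lay at −1.76 (nearest −0.32) and Purkinje cell genes at −1.03 (nearest −0.14). The same array had the highest SD between replicate spots of its series, 0.129 log2 against 0.0819, and the most outlier-marked spots, 248 against 166. Among probes without a gene symbol, which were otherwise used only where all probes were tested each by itself, 8495 of 22133 tested depended on position along C, 605 along H, 75 along L, 2676 along R and 6 along S.

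The share of position-dependent genes in C, 13055 genes, was weighed against a slide change along the series and against array strength. On fractions 1 to 8, all on 1 slide, 4275 genes passed (2439 to 4725 with any 1 of them left out), so a slide change is not the whole cause. With the array's signal as a covariate, 9765 passed (8305 to 10561 with any 1 left out), so array strength is not the whole cause either. Of 100 orders of the C fractions, 1, the real one, gave as many genes, and the highest other gave 10134. Differences between regions of the brain stay open as the biological explanation, and 1 mouse cannot separate them from other changes along the series.

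In the among-series test, 49% of the called genes were highest in R, the series that holds the weakest array. The share was 70.5% of the called genes that were well above background on all 43 arrays and 8.3% of the other, dimmer called genes. Dim genes can hardly be highest on weak arrays, so this contrast does not test the cause. With the array's signal as a covariate, 56.1% of 12008 called genes were highest in R (54.8 to 58.3 with any 1 R fraction left out), so a linear trend with array strength is not the whole cause. A non-linear effect of array strength was not tested. After quantile normalization, 49.8% of 7932 called genes were highest in R (48.2 to 51.1), so scaling to the 75th percentile is not the whole cause. Mouse, plane of cutting and slide stay open and cannot be told apart, since the R arrays lay on slides that held no other series. With the slide as a random block, 1720 genes differed among the series.

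Fractions 1 and 7 of the L series correlated at 0.704 across genes, more than any neighbouring pair (at most 0.579, mean 0.17). Array strength was predicted to bring this value below that of neighbours under another scaling or filter. The value was 0.625 after quantile normalization (neighbours 0.141) and 0.567 over genes on all 43 arrays (0.311). Rescaling does not remove an effect of weak signal itself, and fractions 1, 7 and 8 had the weakest L arrays (75th percentiles 188.5, 198.5 and 185.1). After removal of the trend with array strength, the value fell to 0.267 (−0.193), so array strength stays open as part of the cause. A shared slide also stays open. Of the other fractions on the slide of 1 and 7, fraction 8 correlated with fraction 1 at 0.189 but fractions 4 and 5 at −0.585 and −0.567, against −0.446 to −0.637 for fractions on the other slide. No biological explanation was tested.

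The fractions of 1 series at a time were put in other orders, with the other series in numbered order. Of 100 orders, 1 (the real one) gave as many as 4089 genes in R (highest other 3475) and 249 in S (44), so a chance order can be excluded there. In R, however, the correlation of neighbouring fractions did not pass after adjustment. R fractions 1 and 7, the weakest of the series (75th percentile 52.4 and 108), each lay alone on a slide, and 2 to 6 shared 1. S fractions 1 to 6 and 7 to 10 lay on different slides. Shuffling breaks these layouts too, so an effect of slide or array strength is not excluded. In L, 2 of 100 gave as many as 1147, a share under 0.05, but the other order gave more (1208) and grouped the fractions by slide (2, 3 and 6 ahead of the other 5), so an effect of the slide is not excluded. The slide as a fixed factor cannot decide this, since L fitted by itself called 0 genes both with that factor (limma, 5299 unadjusted) and without it (4957 unadjusted). In H, 7 of 100 orders gave as many as 905 (highest other 1194), so chance cannot be excluded. For the L against R level (108 genes, 1 of 100 splits, highest other 29) and the among-series test (8102, 1 of 100, highest other 1640), chance placement of single fractions can be excluded. Of the 64 splits that part all 7 pairs of same-numbered L and R fractions, 1 gave as many (highest other 1), and 1 with the pairs as a block (43 genes, highest other 2). These splits move fractions between mice and slides, so they exclude neither as the source, and with the slide as a random block the counts were 4 and 1720. For the mirror pairs, the real pairing gave 0 genes, so that all 100 pairings gave as many, the highest other gave 127, and 3 of 99 other pairings gave any. For the L and R curves, with 0 genes, all 100 splits gave as many, and the highest other gave 1075. With real counts of 0 that outcome was fixed and says nothing on chance. Why some other splits gave many genes was not tested. For the sides, the 16 assignments are too few for a share under 0.05, with 0 genes in the real one and 0 in the highest other.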

How the results depend on the processing

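The normexp, fraction number, all-43-array, covariate, C fractions 1 to 8 and R fractions 2 to 6 settings were chosen after the data were seen. Paired by fraction number as a replicate block, L and R differed in level in 43 genes, and the 0 calls for their curves did not change (limma, 1838 at an unadjusted p below 0.05). Among all 5 series, the fraction number as a replicate block gave 9394 genes, but in the other pairs of series same-numbered fractions did not all correlate above 0.1, and in none of the 10 pairs did every fraction correlate best with its own number. Of the counts, correlations and list totals, 336 values stayed on the same side of their threshold or within 1.5 times, 63 moved, 13 became weaker and 2 stronger. Of the values for named genes, 9041 stayed the same, 577 became weaker, 141 stronger and 1 reversed: the side difference of Cox17, well above background in 1 of 10 S fractions, was 1.34 and with normexp −0.09. The planned normexp on mean signals was not run, and all probes each by itself give no value for the gene lists. The all-probe counts are over more features, and for the other settings the cause was not tested. Weak arrays limit dim genes, most of all R fraction 1, with a 75th percentile signal of 52.4.

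With normexp, counts were 5142 in L, 9809 in R, 206 for mirror pairs and 6168 for the L against R level. With quantile normalization, they were 393 in S and 1 for the L and R curves. A filter of 22 arrays gave 124 for mirror pairs. No filter gave 2729 for the L against R level and a neighbour difference of 0.304 in R (p = 0.0599). The filter of all 43 arrays gave 1520 for mirror pairs, 1677 for the level, 17 wide lists in S and a neighbour difference of 0.531 in H (p = 0.0139). All probes gave 25556 in C, 1571 in H, 8090 in R, 48 for the level, 21841 among series, and neighbour differences of 0.277 in L (p = 0.101) and 0.121 in R (p = 0.235). Fits to 1 series gave 8011 in C, 0 in H, 0 in L, 0 in R and 1182 in S. The slide as a random block gave 287 in H, 4 for the level and 1720 among series, with estimated correlations of 0.17 for position, 0.35 for level, 0.199 for curves and 0.438 among series. The slide as a fixed factor in a fit to L alone gave 0, as did that fit without the factor. Numbering R from the other end gave 58 for the level and 896 for the curves, and no spline gave 31 for the level. The covariate gave 139 in L and 452 in R, C fractions 1 to 8 gave 4275 and R fractions 2 to 6 gave 67.

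With 1 fraction left out, counts ran from 10550 to 13579 in C, 370 to 879 in H, 294 to 1447 in L, 713 to 4353 in R and 40 to 227 in S. They ran from 0 to 0 for mirror pairs and sides, 43 to 3518 for the L against R level, 0 to 3 for the curves and 7343 to 8688 among series. Neighbour differences ran from 0.366 to 0.59 in C, 0.049 to 0.589 in H, 0.238 to 0.563 in L, 0.13 to 0.372 in R and 0.158 to 0.295 in S. Wide lists ran from 22 to 27 in C, 22 to 25 in H, 23 to 24 in L, 25 to 27 in R and 24 to 27 in S.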

Other observations

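The test of the glucocorticoid and clock lists, their fits with the slide or the fraction number as a block and that of the L and R numbering were chosen after related values were seen. Few genes depended on position in every series: 39 passed in all 5, 208 in 4, 731 in 3, 2933 in 2, 10359 in 1 and 4226 in none. Ttr, the transthyretin of choroid plexus, was singled out after its values were seen. Its fitted range was 7.10 ± 1.71 log2 in H (limma, adjusted p = 0.0355) and 8.08 ± 1.54 in R (adjusted p = 0.00254), with 182-fold and 222-fold between the highest and the lowest fraction, while in C it did not pass (adjusted p = 0.22).

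Same-numbered L and R fractions resembled each other, with a mean correlation across genes of 0.423, against 0.165 with the R series reversed and 0.271 with the numbers shifted by 1. Over all 5040 orders of the R fractions the exact permutation p was 0.000198 (one-sided). This is consistent with mirrored anatomy numbered from the same end in both series, which the labels do not state.

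Hif3a, Depp1 and Nfkbia, among the 5 genes with the smallest p between L and R, are known to respond to glucocorticoids, which led to a hypothesis on the mouse of the R series. A list of 14 glucocorticoid-responsive genes without these 5 had a median R minus L difference of 0.72 log2, at percentile 100 of matched random lists, and lay 0.85 above the other 4 series. In R, 13 of 14 were higher than in L, 7 passed over all genes and 10 when adjusted over the list alone, among them Sgk1 (3.66 in R, 2.03 to 2.56 elsewhere), Fkbp5 and Tsc22d3. With the slide as a random block, limma called 0 of 14 over all genes (10 at an unadjusted p below 0.05, 10 adjusted over the list alone), and with the fraction number as a block 4 (10 adjusted over the list alone). Of the lists fixed beforehand, those of red blood cells (median 1.71, 3 of 3 higher in R), ribosomal proteins (0.66), pituitary and pineal (0.53), microglia (0.47), astrocytes (0.42) and meningeal fibroblasts (0.41) also lay above the 95th percentile, while endothelial genes had 0.08 at percentile 45.3. The values may reflect a stress hormone response in that mouse, but a difference in blood or in the cells sampled stays open, mouse and slide cannot be told apart, and H was near R for Fkbp5 (2.32 and 2.47) and Zbtb16 (2.65 and 2.85). Plin4 and Lcn2 were higher in H (1.84 and −1.01) than in R (1.15 and −1.36), and the other listed members were lower in H than in R. A different time of day stays open. The 9 clock genes had a median absolute difference of 0.16 log2 at percentile 18.4, but 3 passed adjusted over the list alone (1 with the slide as a random block): Dbp (0.76 in R minus L), Tef (0.31) and Arntl (−0.42). Dbp and Arntl are known to peak at opposite times of day, and genes of different phase need not all differ between a pair of times, so that the median does not exclude it.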
